A study of Mus musculus with 63 samples.

How the data were processed

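The data were 22 tables of RNA-seq read counts per gene, 1 per library, deposited by the authors for mouse embryonic stem (ES) cells kept in 2i medium, extended pluripotent stem (EPS) cells kept in LCDM medium, and cells derived from them. Per the labels the cells grew on inactivated mouse embryonic fibroblast feeders or on Matrigel, without saying which library came from which. The values are whole-number counts with no normalization, over 47517 gene symbols. Each table ends in the summary lines that HTSeq writes, though no counting tool, version or strand setting is named. Of all lines 5.61 to 8.62% were reads outside annotated genes and 3.70 to 5.32% ambiguous reads. Reads with more than 1 alignment made up 5.45 to 6.66%. The submitters' notes name CASAVA, Bowtie2 2.3.2, mm10 and GRCm38.p6 for the series without giving their role for RNA-seq. The other 41 samples hold no count table of this kind.

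Counts on genes came to 13672061 to 20782348 per library, and 19687 to 22188 symbols had a count above 0. A gene with 0 counts in a library can reach between 0.144 and 0.219 CPM (gene counts scaled to a common library total), taking 3 counts as the floor, which covers counting error only. Coordinates came from the GRCm38.p6 annotation, in which 34757 symbols were found, and 94.8% of the genes tested in undifferentiated cells. Of 586 symbols in the fixed lists 580 were in the tables. A fold against a group with 0 counts in all its libraries was computed against a floor of 3 counts per library and is given as a lower bound. Intervals and floors leave out any variation between cultures.

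Samples were grouped by their titles into 10 groups of 2 or 3 libraries. The 3 models were fitted with edgeR 4.0.16 in R 4.3.3, using TMM factors, the filterByExpr filter and the robust quasi-likelihood F-test. One held the 14 undifferentiated libraries in 6 groups, 1 the 8 day 6 libraries in 4 groups and 1 the 16 hairpin and overexpression libraries of both stages in 8 groups, from which the change of each effect between stages was tested. The first 2 models gave EPS against ES, shYy1 against shCtrl, oeYy1 against oeCtrl and, on day 6, both manipulations and shCtrl against oeCtrl. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. A second count took called genes with an absolute log2 fold change of at least 1. Day 6 against undifferentiated cells of each line was taken from the third model.

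The gene lists, the tests and the rule for named genes were fixed before the data were examined. The named genes of each of the 6 comparisons given by the first 2 models are Yy1, the 8 largest rises and 8 largest falls among called genes with an average of at least 5 CPM and groups that do not overlap, up to 4 called genes of smallest p from each list, and 12 genes given in each of these 6 comparisons whether called or not. The 12 are Dnmt3l, Kdm5c, Hdac6, Nanog, Pou5f1, Sox2, Klf4, Gata4, Gata6, Sox17, Pdgfra and Cdx2. Unnamed clones and pseudogenes were left out of the largest changes. Groups without overlap arise by chance in 10% of genes with 3 against 3 libraries and in 33.3% with 2 against 2. The 28 lists cover naive, core, formative and 2-cell-like pluripotency, DNA methylation, H3K4 methylation and histone deacetylation, primitive endoderm, trophoblast, mesendoderm, neuroectoderm, fibroblasts, ERK, Wnt and LIF-STAT3 targets, and glycolysis. They also cover oxidative phosphorylation, the mitochondrial genome, cholesterol synthesis, ribosomal proteins, imprinted and germline genes, cohesin, INO80, PRC2, p53 targets, interferon-stimulated genes, G2/M and sex-linked genes.

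Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 between genes and again with an estimated correlation, and with fry, which asks whether a list moves to 1 side on balance without comparing it with other genes. Adjusted p values were taken over the lists of a comparison. EPS-high and ES-high genes were the genes called at least 2-fold apart between EPS and ES and were tested as lists in the other comparisons. The position on the line from ES to EPS was the projection of log2 CPM (prior count 2) of the called genes, with an exact two-sided permutation test. The comparison of EPS shCtrl with ES oeCtrl and the medians per chromosome were added after the data were seen.

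The models were tested on simulated data, drawn with the real library sizes and the estimated spread, in which 200 genes per comparison were changed. Of genes changed 1.5-fold, 2-fold and 4-fold, 32.8, 74.6 and 97.0% were called for EPS against ES, 35.8, 59.7 and 89.4% for depletion and 23.9, 68.7 and 90.9% for overexpression. On day 6 the shares were 70.1, 89.6 and 98.5% for the hairpin and 74.6, 92.5 and 98.5% for the construct. For the change between stages they were 23.9, 64.2 and 81.8% (depletion) and 35.8, 74.6 and 83.3% (overexpression), and between 3.15 and 7.53% of calls were false. No pair of replicates was a copy. Whether replicate numbers pair libraries was checked by correlating the deviations from the group means across genes. For ES and EPS libraries of the same number r was 0.245, 0.331 and 0.545, across genes that are not independent, and between replicates 1 and 2 of both states 0.344 and 0.325. Replicate 3 stood apart from the others, at between -0.456 and -0.379. Each same-number pair passed 0.1, so the numbers were taken to pair these 6 libraries, although the labels name no shared batch. The models had no block, as set beforehand, and a fit with the replicate number as a block was an alternative.

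Alternatives set beforehand were RLE factors, no count filter or a filter of 1 CPM in 2 libraries, DESeq2 1.42.0, limma-voom, the replicate block, only the libraries compared, each library left out in turn, other thresholds for the derived lists, fry and the estimated correlation, and other genes or a prior count of 0.5 for the line. Added after the data were seen were leaving out genes or list members on chromosomes X and Y, leaving out chromosomes 6, 8, X and Y, leaving out replicate 3 of both ES and EPS, and keeping only genes of at least 1 CPM over the 8 hairpin and overexpression libraries.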

Results

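The series holds 63 mouse samples on YY1, a zinc finger transcription factor, in ES and EPS cells. EPS is a cultured state reported to reach both embryonic and extraembryonic lineages. RNA was counted in 22 of them, which form 10 groups, and the other 41 samples (chromatin accessibility, factor binding, histone marks, chromatin contacts, DNA methylation and single-cell RNA) were not analysed here. The groups were ES and EPS cells (n = 3 each), EPS cells with a control or a Yy1 short hairpin RNA (shCtrl and shYy1, n = 2 each) and ES cells with a control or a Yy1 overexpression construct (oeCtrl and oeYy1, n = 2 each). The last 4 groups were also sampled on day 6 of a condition that the labels name F4H (n = 2 each). The sample titles call the day 6 controls shCtrl and oeCtrl, but the names of their deposited tables give no construct, so these controls may be cells without one. The titles were followed. The labels do not say where the replicates came from, so p-values measure only the spread between these samples, which may be technical. Levels are given in CPM, as mean ± SD. Changes are log2 fold changes ± SE of the first-named group against the second.

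Yy1 itself lies on chromosome 12 (start 108792945, end 108820148, GRCm38.p6). It stood at 125 ± 7.19 CPM in EPS cells (n = 3) and 123 ± 9.78 CPM in ES cells (n = 3). The difference was not called (log2 0.02 ± 0.09, adjusted p = 0.907). The hairpin lowered it from 131 ± 6.80 to 67.0 ± 0.213 CPM (log2 -0.99 ± 0.11, adjusted p = 4.43e-06). The construct raised it from 122 ± 4.75 to 926 ± 8.44 CPM (log2 2.94 ± 0.11, adjusted p = 4.91e-11). On day 6 of F4H the shYy1 cells held 111 ± 2.23 CPM and the shCtrl cells 114 ± 3.67 CPM (log2 -0.03 ± 0.05, adjusted p = 0.567). The oeYy1 cells held 317 ± 2.66 CPM on that day, against 125 ± 3.64 CPM in their control (log2 1.38 ± 0.05, adjusted p = 9.22e-33).

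**Figure D1:**
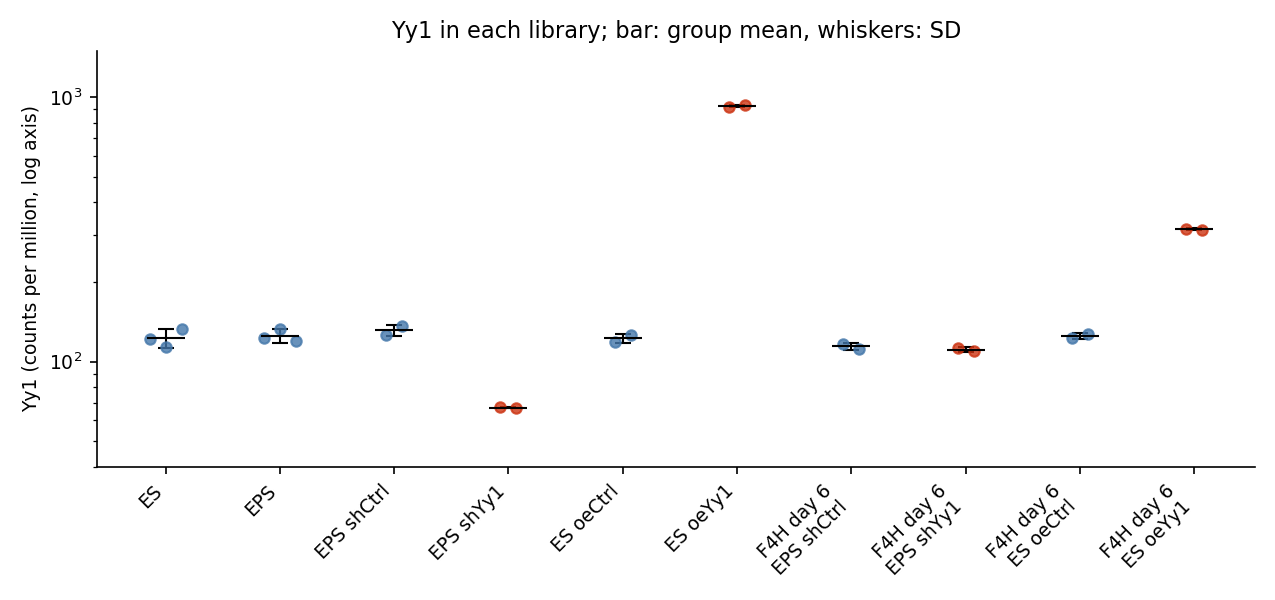
Yy1 in CPM on a log axis for the 22 libraries in 10 groups, with each point a library, the bar the group mean and the whiskers the SD (n = 2 or 3). Undifferentiated shYy1 and oeYy1 means were 67.0 and 926 CPM, and day 6 shYy1 and shCtrl means 111 and 114 CPM.

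The comparison of EPS with ES cells asked how the transcriptomes of the 2 states differ. Levels on chromosomes 6 and 8 also parted them, so state and cell line may be confounded, also in derived lists and positions. Genes that answer to ERK signalling were higher in EPS cells. Egr1, an immediate early transcription factor, stood at 139.7 ± 51.0 against 7.65 ± 0.630 CPM (log2 4.18 ± 0.26, adjusted p = 4.45e-08). Spry4, a feedback inhibitor of receptor tyrosine kinases, stood at 99.3 ± 29.8 against 6.40 ± 1.18 CPM (log2 3.94 ± 0.21, adjusted p = 2.21e-09). Dusp6, a phosphatase that switches ERK off, rose by 1.73 and Spry1 by 1.63 on the log2 scale. In the ERK list 14 of 18 members rose and 1 fell (14 and 1 adjusted over the list alone). The list was higher than other genes (camera, adjusted p = 2.09e-09, adjusted p = 0.0261 with an estimated correlation).

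Some genes of DNA methylation differed between EPS and ES cells, though their list as a whole did not pass. Dnmt3a and Dnmt3b, the de novo methyltransferases, stood at 35.6 ± 7.80 against 10.0 ± 1.12 CPM and 156 ± 49.8 against 32.4 ± 2.75 CPM (log2 1.82 and 2.25). Dnmt3l, their catalytically inactive partner (chromosome 10, start 78042287, end 78063622), stood at 48.5 ± 4.87 against 15.5 ± 5.36 CPM (log2 1.63 ± 0.22, adjusted p = 7.28e-05). Tet2, which oxidises methylcytosine, fell by 1.54. Of the DNA methylation machinery as a whole 5 of 18 members rose and 3 fell (5 and 3 adjusted over the list alone), and the list did not pass (camera, adjusted p = 0.392). In the list of formative and primed epiblast genes, which shares Dnmt3a and Dnmt3b with it, 8 of 18 members rose and 2 fell (8 and 3 adjusted over the list alone, camera adjusted p = 0.00739, adjusted p = 0.345 with an estimated correlation).

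Among pluripotency genes, the let-7 inhibitors Lin28a (534 ± 37.0 against 95.8 ± 12.1 CPM, log2 2.47) and Lin28b (log2 2.14) and the chromatin factor Utf1 (log2 1.40) rose. Nanog (616 ± 82.0 against 1047 ± 28.5 CPM, log2 -0.78 ± 0.10, adjusted p = 2.42e-05), Sox2 (log2 -0.41) and Fgf4 (log2 -0.67) fell, and Klf4 rose (log2 0.50). Pou5f1 was called neither way (log2 0.00, adjusted p = 0.988). Kdm5c, a histone demethylase, was not called (log2 -0.22, adjusted p = 0.0954, or 0.0228 without EPS replicate 3), but it was with the replicate number as a block. Hdac6, a deacetylase, passed narrowly (log2 -0.26, adjusted p = 0.0443), and its call ended without ES replicate 1 or 2 or EPS replicate 1 or 3 (at most 0.124), without a count filter (0.0771), with only the libraries compared (0.0774), with RLE factors (0.0577) and without replicate 3 of both states (0.0661). Of the core pluripotency list 4 of 12 members rose and 1 fell (4 and 1 adjusted over the list alone, camera adjusted p = 0.0510, or 0.0271 with the replicate number as a block). Of the naive list 5 of 20 members rose and 7 fell (6 and 7 adjusted over the list alone, adjusted p = 0.676). Of the glycolysis list 10 of 21 members rose and 2 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.00377, adjusted p = 0.588 with an estimated correlation). Pdk1, a kinase that holds back pyruvate dehydrogenase, stood at 209.9 ± 3.12 against 41.8 ± 4.90 CPM. Pfkl, a phosphofructokinase, rose by 0.94, and Hk2, a hexokinase, fell by 0.86.

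Fibroblast and endoderm genes were lower in EPS than in ES cells. In the fibroblast list, written to track feeder cells, 0 of 22 members rose and 15 fell (0 and 16 adjusted over the list alone, camera adjusted p = 2.85e-10, adjusted p = 0.466 with an estimated correlation). Its members Col5a2, a fibrillar collagen (22.0 ± 13.7 against 194 ± 48.5 CPM), and Fbn1, which forms microfibrils (16.2 ± 9.91 against 108 ± 36.6 CPM), fell by 3.15 and 2.75. The list sum was 3244 to 5746 CPM in ES and 591 to 1463 CPM in EPS libraries. Of the primitive and extraembryonic endoderm list 3 of 27 members rose and 10 fell (3 and 10 adjusted over the list alone, camera adjusted p = 0.0281, adjusted p = 0.321 with an estimated correlation), a call that was lost without EPS replicate 1 (adjusted p = 0.0729). The matrix glycoprotein Sparc (312 ± 9.94 against 1065 ± 175 CPM) fell by 1.79, and the laminin chains Lama1 and Lamc1 by 0.70 and 0.79. Gata4 fell by 0.80 (adjusted p = 0.0110, or 0.0638 without EPS replicate 2 and 0.0550 with only the libraries compared). Gata6, Sox17, Pdgfra and Cdx2 were not called (adjusted p between 0.243 and 0.701, with 0.0396 for Pdgfra under the block). Of the 5 sex-linked genes 3 fell, also 3 adjusted over the list alone (camera, adjusted p = 0.00739, adjusted p = 0.321 with an estimated correlation), among them the Y-linked RNA helicase Ddx3y (log2 -2.47).

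The steepest changes here and below are among called genes with an average of at least 5 CPM and groups that do not overlap, and genes at lower levels could change more. Besides Egr1, steep rises were in Dll1, a Notch ligand (log2 4.37), Elavl3, a neuronal RNA-binding protein (4.03), and Crmp1, which acts in axon guidance (3.99). The steepest falls by this rule were in the ion channel gene Pkd2l1 (log2 -7.64), in Arl14epl (-5.32) and in Fkbp6, which acts in meiosis (-5.25). Of 16440 genes tested, 5033 were called, 2261 higher and 2772 lower in EPS cells. A change of at least 2-fold was reached by 787 of the higher genes, named EPS-high below, and by 1124 of the lower, named ES-high. The other 22 fixed lists did not pass, at adjusted p between 0.0510 and 0.972. With the block the ribosomal protein list passed as higher (0.00260, 13 of 53 members up and 1 down).

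The next comparison asked which genes changed when Yy1 was depleted in EPS cells, and most ERK target genes were lower with the hairpin. Myc, a growth-promoting transcription factor, fell from 64.3 ± 12.9 to 8.27 ± 1.55 CPM (log2 -2.97 ± 0.22, adjusted p = 6.29e-08) and Spry4 from 93.7 ± 2.69 to 15.0 ± 0.902 CPM (log2 -2.67). Spry2 and Spred1, inhibitors of the same pathway, fell by 1.75 and 1.39. Of the ERK list 1 of 18 members rose and 10 fell (1 and 10 adjusted over the list alone, camera adjusted p = 1.21e-06, adjusted p = 0.00662 with an estimated correlation). Lin28a fell from 329 ± 149.9 to 71.4 ± 0.907 CPM (log2 -2.22), with Lin28b (log2 -1.62), Utf1 (-1.63) and the RNA-binding protein L1td1 (-1.14). In the core pluripotency list 1 of 12 members rose and 8 fell (1 and 8 adjusted over the list alone, camera adjusted p = 5.81e-05, adjusted p = 0.0152 with an estimated correlation). X-linked and Y-linked genes were higher in the same shYy1 libraries, with an X-linked median log2 fold change of 0.83.

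Among genes of DNA methylation, Dnmt3l fell from 55.9 ± 17.5 to 8.56 ± 2.09 CPM (log2 -2.73 ± 0.29, adjusted p = 1.00e-05) and Dnmt3a from 222 ± 17.2 to 93.1 ± 2.63 CPM (log2 -1.27). Dnmt3b fell by 1.18 (adjusted p = 0.00366, or 0.0608 without EPS shCtrl replicate 2), and Zfp57, which keeps imprints methylated, by 0.85. In the list of DNA methylation machinery 3 of 18 members rose and 7 fell (3 and 8 adjusted over the list alone), which did not pass as a set (camera, adjusted p = 0.137). Nanog rose from 537 ± 16.1 to 1121 ± 63.3 CPM (log2 1.04 ± 0.13, adjusted p = 1.33e-05), and so did Fgf4 (log2 1.18), the AKT coactivator Tcl1 (1.89) and Prdm14, a regulator of naive pluripotency (1.16). The naive list went both ways, with 7 of 20 members up and 7 down, the same numbers adjusted over the list alone (adjusted p = 0.844). Pou5f1 was not called (log2 -0.31, adjusted p = 0.134). Sox2 (log2 0.32, adjusted p = 0.0431) and Klf4 (-0.32, adjusted p = 0.0473) passed narrowly. Without 1 library (EPS shCtrl replicate 2 or either shYy1 replicate for both genes, EPS shCtrl replicate 1 for Klf4) the adjusted p was at most 0.251 and 0.223. Both calls also ended without a count filter (0.0834 and 0.0687) and with only the 4 libraries compared (0.0631 and 0.0788), and that of Klf4 with RLE factors (0.0524) and without X-linked and Y-linked genes (0.0611).

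Primitive endoderm genes were lower after depletion. The endoderm transcription factor Gata6 fell from 18.9 ± 7.60 to 4.53 ± 1.08 CPM (log2 -2.08 ± 0.40, adjusted p = 9.70e-04), the visceral endoderm receptor Cubn by 2.69 and the activin-binding Fst by 1.98. Sparc rose by 1.03 and the coactivator Cited1 by 2.62. Of the endoderm list 3 of 27 members rose and 13 fell (3 and 14 adjusted over the list alone, camera adjusted p = 0.0177, adjusted p = 0.144 with an estimated correlation). Pdgfra, a growth factor receptor of primitive endoderm, fell by 1.63 (adjusted p = 0.00559, or 0.0622 without EPS shYy1 replicate 2). Gata4 fell by 0.78 (adjusted p = 0.0211), with adjusted p of at most 0.148 without EPS shCtrl replicate 2 or either shYy1 replicate. Sox17 (log2 -0.83, adjusted p = 0.172) and the trophoblast factor Cdx2 (-0.67, adjusted p = 0.552) were not called.

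Targets of p53 were higher after depletion, with 9 of 19 up and 2 down (10 and 2 adjusted over the list alone, camera adjusted p = 0.0380, adjusted p = 0.165 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose from 90.0 ± 19.5 to 219.9 ± 30.9 CPM, the receptor Eda2r by 1.37 and the death-promoting Pmaip1 by 1.13 on the log2 scale. This call was lost without EPS shCtrl replicate 1 (adjusted p = 0.145) and without the X-linked and Y-linked members (0.0691). The test of camera pointed down for 3 further lists, few members of which were called. INO80 complex genes, which encode partners of YY1, had a median of -0.24 (3 of 13 down and 0 up, 5 and 0 adjusted over the list alone, adjusted p = 0.0469, adjusted p = 0.667 with an estimated correlation). Ribosomal protein genes had a median of -0.18 (1 of 53 down, none up, 0 either way adjusted over the list alone, adjusted p = 0.0115, adjusted p = 0.900 with an estimated correlation). Oxidative phosphorylation genes had one of -0.17 (4 of 51 down, none up, 0 either way adjusted over the list alone, adjusted p = 0.0416, adjusted p = 0.900 with an estimated correlation). All 3 calls were lost without EPS shCtrl replicate 2 (adjusted p = 0.335, 0.335 and 0.338 in that order, with medians of -0.129 for INO80 and -0.105 for ribosomal protein genes), and those of INO80 and oxidative phosphorylation also without EPS shYy1 replicate 2 (0.0591 and 0.0591). That of INO80 also ended with RLE factors (0.0509), and the others had 0.484 by fry (ribosomal protein) and 0.519 by fry (oxidative phosphorylation).

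X-linked and Y-linked genes were higher in shYy1 than in shCtrl cells. Among 607 tested X-linked genes 351 rose and 15 fell, with a median log2 fold change of 0.83, 0.86 above the autosomal median (camera over chromosomes, adjusted p = 3.13e-29, 3.25e-05 with an estimated correlation). The X-linked histone demethylase Kdm5c stood at 363 ± 25.9 against 209 ± 5.43 CPM (log2 0.77 ± 0.12, adjusted p = 1.42e-04) and the X-linked deacetylase Hdac6 at 232 ± 2.55 against 100.2 ± 13.1 CPM (log2 1.19 ± 0.12, adjusted p = 1.76e-06). The Xlr genes, an X-linked family whose near-identical copies share reads, had the steepest rises, so their values are uncertain. With 0 counts in both shCtrl libraries and a floor of 3 counts per library, Xlr5a was at least 200.0-fold and Xlr5b at least 149-fold higher. Of the 5 sex-linked genes 4 rose, also 4 adjusted over the list alone (camera, adjusted p = 2.67e-04, adjusted p = 0.0595 with an estimated correlation), and Y-linked Eif2s3y, a translation factor, went from 0.537 ± 0.338 to 46.3 ± 4.77 CPM. Y-linked genes summed to 3.07 ± 0.0371 CPM in shCtrl and 148 ± 1.05 CPM in shYy1 libraries (n = 2 each). In the fibroblast list 8 of 22 members rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.152). The collagen genes Col1a1 (from 0.626 ± 0.125 to 6.04 ± 1.02 CPM) and Col1a2 (from 0.328 ± 0.211 to 5.20 ± 0.729 CPM) were at low levels in both groups. The list summed to 247 ± 26.1 CPM in shCtrl and 181 ± 0.164 CPM in shYy1 libraries, of which the secreted glycoprotein gene Fstl1 made up 202 ± 31.2 and 88.6 ± 7.28 CPM.

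**Figure D2:**
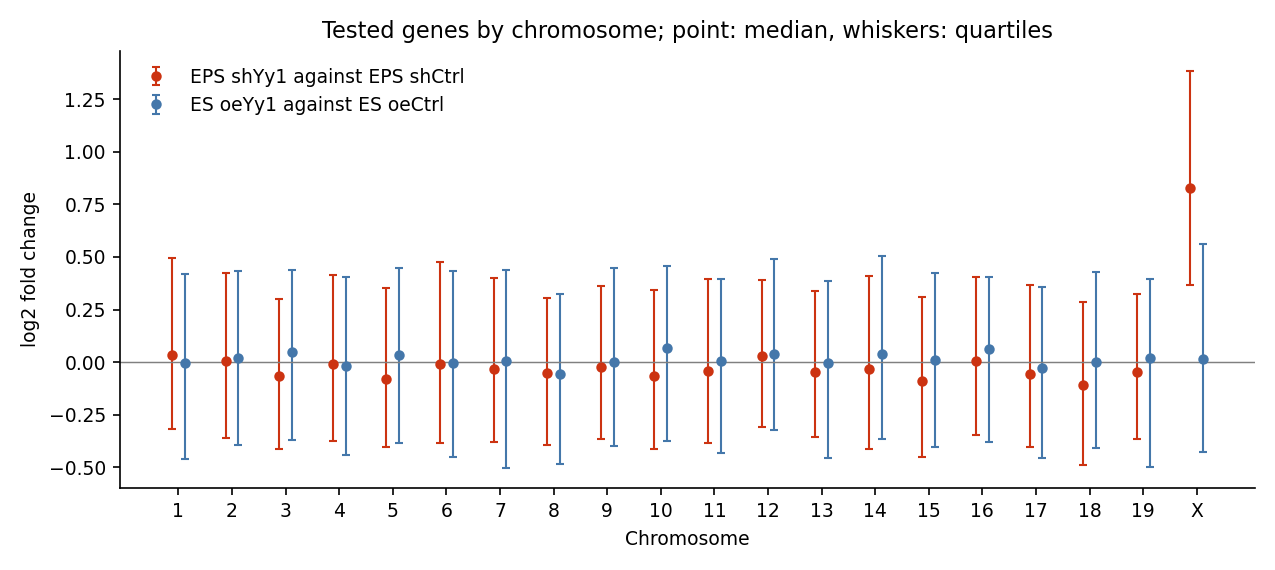
Median log2 fold change of the tested genes on each chromosome, with whiskers from the lower to the upper quartile, for Yy1 depletion in EPS cells and Yy1 overexpression in ES cells (n = 2 libraries in each group). Chromosome X stood at 0.83 after depletion and 0.02 after overexpression.

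In the depletion comparison 4682 of 16440 genes were called, 2490 higher and 2192 lower in shYy1 cells, and 1928 of them changed at least 2-fold. Between 2571 and 4853 genes were called when 1 library was left out. Among the steepest falls were Enox1, a cell surface oxidase (log2 -4.21), Soga3 (-4.02) and Nt5e, which makes adenosine outside cells (-3.44). The 20 lists that did not pass had adjusted p between 0.0793 and 0.907.

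Overexpression of Yy1 in ES cells, the reverse manipulation, asked which genes follow a higher Yy1 level. Y-linked genes were lower in oeYy1 than oeCtrl cells, so more than Yy1 may differ. The DNA methylation gene Dnmt3l went from 2.62 ± 0.149 to 222 ± 10.3 CPM (log2 6.42 ± 0.35, adjusted p = 1.95e-08), Dnmt3b from 39.4 ± 1.24 to 117 ± 2.00 CPM (log2 1.59), and Dnmt3a rose by 1.06 and Zfp57 by 0.93. Their DNA methylation list did not pass, and 6 of 18 members rose and 3 fell (6 and 3 adjusted over the list alone, camera adjusted p = 0.221). Of the ERK targets, Myc stood at 18.7 ± 1.33 against 1.14 ± 0.0178 CPM (log2 4.04 ± 0.28, adjusted p = 3.94e-08), Spry4 at 15.2 ± 1.79 against 1.58 ± 0.213 CPM (log2 3.28), Dusp6 rose by 1.18 and the cyclin gene Ccnd1 by 2.21. In this list 7 of 18 members rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.106 with an estimated correlation). Lin28a rose by 1.45 and L1td1 by 0.77. In the core pluripotency list 6 of 12 members rose and 0 fell (7 and 0 adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.106 with an estimated correlation).

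Cholesterol synthesis genes fell together with overexpression. Srebf2, the transcription factor that drives the pathway, went from 713 ± 24.5 to 362 ± 9.01 CPM (log2 -0.96 ± 0.12, adjusted p = 1.09e-05), the sterol transporter Stard4 fell by 1.26, and the sterol sensor Insig1 by 0.84. In the list 1 of 23 members rose and 18 fell (1 and 18 adjusted over the list alone, camera adjusted p = 1.96e-06, adjusted p = 0.292 with an estimated correlation). Imprinted genes went up more often than down. In their list 12 of 31 members rose and 5 fell (12 and 6 adjusted over the list alone, camera adjusted p = 0.0168, adjusted p = 0.477 with an estimated correlation). The long noncoding RNAs Rian, Meg3 and Mirg, which lie in 1 imprinted region on chromosome 12 and are expressed from the maternal copy, rose by 1.93, 2.18 and 2.35. After depletion in EPS cells Rian (log2 -1.77) and Meg3 (-1.63) fell. Targets of p53 were lower with overexpression, where 1 of 19 members rose and 9 fell (2 and 10 adjusted over the list alone, camera adjusted p = 0.0282, adjusted p = 0.188 with an estimated correlation, or 0.0606 without X-linked and Y-linked members). Pmaip1 fell by 2.86, Cdkn1a by 1.15 and Btg2, which restrains proliferation, by 1.31, while Perp, a membrane protein of apoptosis, rose by 1.80.

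Nanog was not called (log2 0.24, adjusted p = 0.163). Pou5f1 (log2 0.51, adjusted p = 0.0171), Sox2 (0.31, adjusted p = 0.0447) and Klf4 (0.35, adjusted p = 0.0313) passed with all libraries, and leaving out any 1 of the 4 oeCtrl and oeYy1 libraries ended each call (adjusted p of at most 0.101, 0.280 and 0.220), as did the lack of a count filter for Sox2 (0.103) and Klf4 (0.0540). Gata4 fell from 12.0 ± 1.15 to 5.37 ± 0.204 CPM (log2 -1.14), and Gata6, Sox17, Pdgfra and Cdx2 were not called (adjusted p between 0.111 and 0.672). Kdm5c (log2 0.04, adjusted p = 0.813) and Hdac6 (-0.12, adjusted p = 0.453) were not called either. The 2-cell-like list passed (5 of 13 up and 1 down, also adjusted over the list alone, adjusted p = 0.0282, adjusted p = 0.391 with an estimated correlation) on Usp17le and Zscan4 copies that share reads and had near 0 counts, so this call is uncertain. Its median was 3.82 as fitted and 1.23 with genes at 0 set to their bound, and it was lost without ES oeCtrl replicate 2 or ES oeYy1 replicate 2 (0.0594 and 0.0617) and with the replicate block (0.0707). Of the sex-linked genes 3 of 5 fell, also 3 adjusted over the list alone (camera, adjusted p = 0.0115, adjusted p = 0.106 with an estimated correlation). Y-linked genes summed to 121 ± 16.5 CPM in oeCtrl and 26.6 ± 0.365 CPM in oeYy1 libraries.

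**Figure D3:**
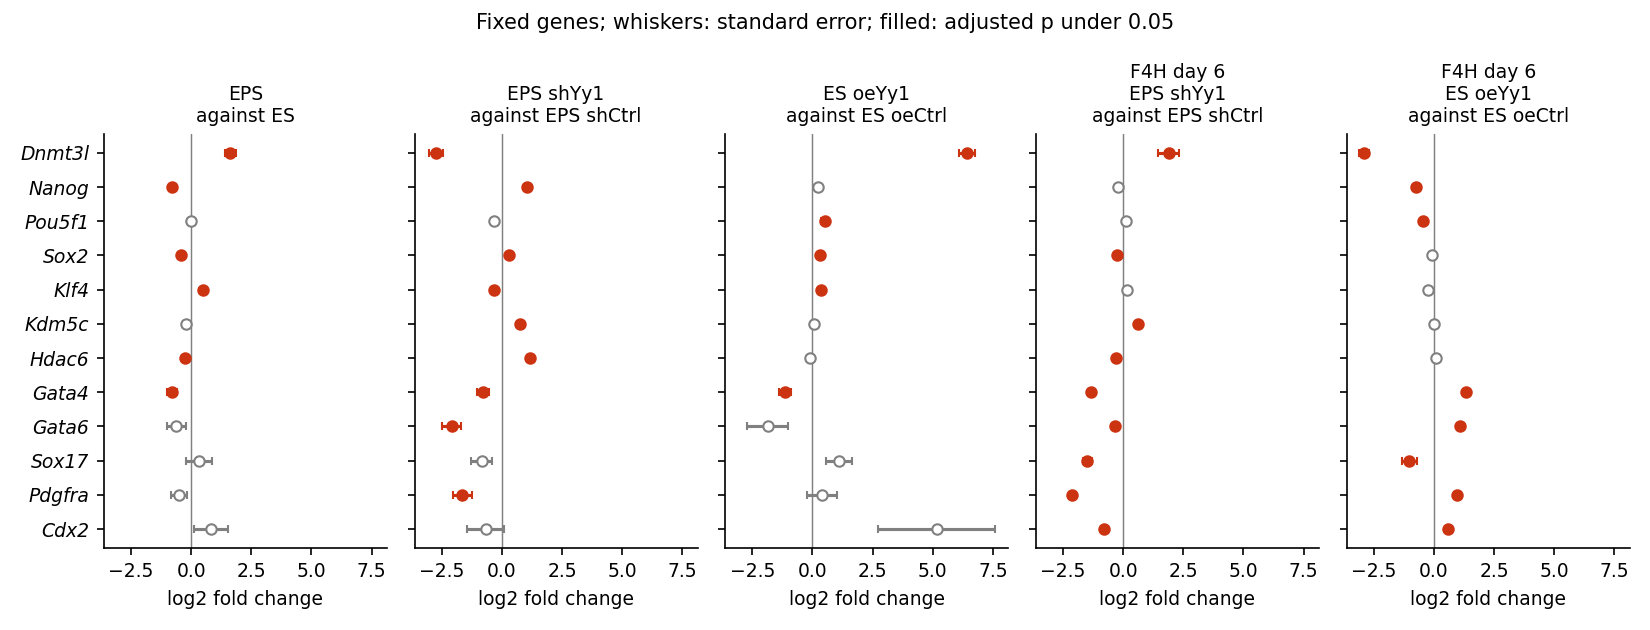
Log2 fold change with standard error for 12 genes named before the data were examined, in 5 comparisons, with filled points for adjusted p under 0.05 (n = 3 libraries per group for EPS against ES, otherwise 2). Dnmt3l fell by 2.73 after depletion in EPS cells and rose by 6.42 after overexpression in ES cells, and the 2 day 6 values were 1.89 and -2.90.

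With overexpression 5255 of 16440 genes were called, 2441 higher and 2814 lower, and 2443 of them changed at least 2-fold. The count fell without 1 library and was 8149 with only the oeCtrl and oeYy1 libraries. Among genes of at least 5 CPM on average, the steepest rises after Dnmt3l were in Crym, a thyroid hormone binding protein (log2 6.17), the chemokine Cx3cl1 (4.98) and the transcriptional regulator Aire (4.56). Among the steepest falls were Aldh1a3, which makes retinoic acid (log2 -6.23), and the chitinase gene Chit1 (-5.57). The 21 lists that did not pass had adjusted p between 0.0665 and 0.806. No list call of this comparison held with an estimated correlation. In EPS against ES only the ERK list held, and after depletion only the ERK and core pluripotency lists.

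Genes that differ between EPS and ES cells lay closer to the ES level in shYy1 than in shCtrl cells. The same shYy1 libraries held higher X-linked and Y-linked genes, so neither this shift nor the positions on the line below can be credited to Yy1 alone. Of 787 EPS-high genes 213 fell and 42 rose (228 and 49 adjusted over the list alone, median -0.48, camera adjusted p = 1.21e-06, adjusted p = 0.00338 with an estimated correlation). Of 1124 ES-high genes 475 rose and 40 fell (507 and 46 adjusted over the list alone, median 0.90, camera adjusted p = 6.85e-16, adjusted p = 0.0407 with an estimated correlation). Both lists were chosen on the ES and EPS libraries of this series, so their direction in those libraries is not independent evidence. With overexpression in ES cells 202 EPS-high genes rose and 112 fell (218 and 119 adjusted over the list alone, median 0.40, camera adjusted p = 0.0168, adjusted p = 0.106 with an estimated correlation, 0.0537 without ES oeCtrl replicate 2, and 0.553 for the list with no fold threshold). Of the ES-high genes 207 rose and 274 fell there (223 and 284 adjusted over the list alone, camera adjusted p = 0.465).

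On a line through the mean ES (0) and mean EPS (1) profile of the 5033 called genes, shCtrl libraries lay at 0.846 and 0.963 and shYy1 libraries at 0.424 and 0.439. The oeCtrl libraries lay at 0.210 and 0.216 and the oeYy1 libraries at 0.327 and 0.350, a mean difference of 0.126 that was 0.0827 without EPS replicate 3. With 2 against 2 libraries the exact two-sided permutation p was 0.333 for each pair, the smallest this design allows. Of the genes changed at least 2-fold, 222 fell after depletion and rose with overexpression, where 46.8 would be shared if the lists were independent, and 344 rose after depletion and fell with overexpression, where 97.6 would be. Among the first were Dnmt3l, Myc, Spry4, Id3 and Enox1. The largest changes of the second were in Xlr copies, which share reads, and 28 of its genes were X-linked and 4 Y-linked, among them Ddx3y and Eif2s3y, which also rose in day 6 shYy1 cells, where Yy1 was not lower (log2 4.03 and 3.64). Outside chromosomes X and Y, counted after the data were seen, 218 and 312 genes were shared, where 45.9 and 81.2 would be. Genes are not independent of each other, so no p is given for these overlaps. Both pairs differed on chromosome Y, so the overlaps cannot be credited to Yy1 alone.

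The hairpin and overexpression controls, compared after the data were seen, differed in the direction of EPS against ES. Of the EPS-high genes 477 were higher and 21 lower in EPS shCtrl than in ES oeCtrl cells (501 and 24 adjusted over the list alone, camera adjusted p = 4.30e-23, adjusted p = 6.10e-05 with an estimated correlation). In the ERK list 12 of 18 members rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 2.13e-07, adjusted p = 0.00453 with an estimated correlation), and in the primitive endoderm list, which was lower in EPS than in ES cells, 14 of 27 members rose and 2 fell (15 and 2 adjusted over the list alone, adjusted p = 0.00327, adjusted p = 0.0405 with an estimated correlation). In the fibroblast list 6 of 22 members rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.304). Of 28 lists 13 passed, of which only the ERK, core pluripotency and primitive endoderm lists held with an estimated correlation, and the 15 others had adjusted p between 0.0655 and 0.928.

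**Figure D4:**
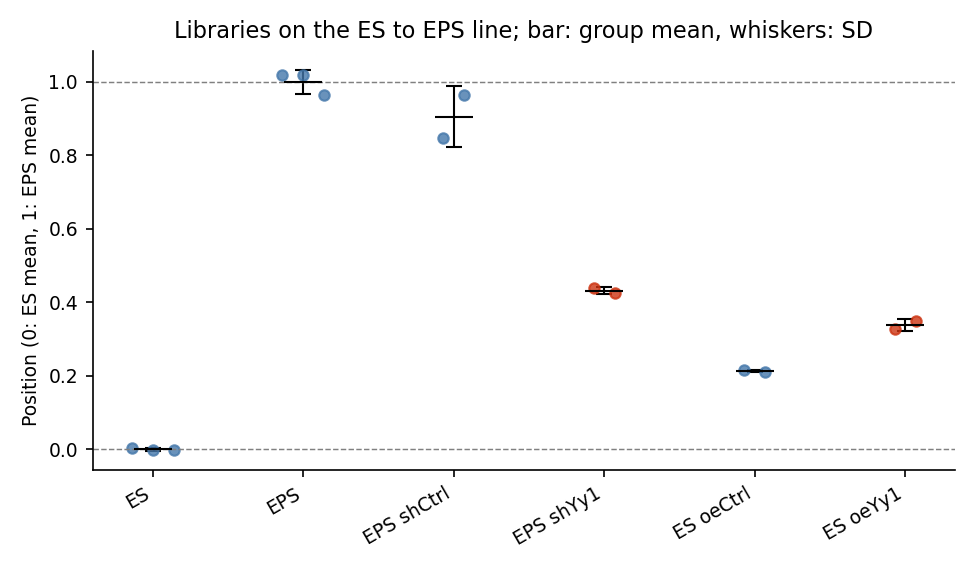
Position of each of the 14 undifferentiated libraries on the line from the mean ES profile (0) to the mean EPS profile (1), with the bar at the group mean and whiskers for the SD (n = 2 or 3). The shYy1 mean was 0.432 against 0.905 in shCtrl, and the oeYy1 mean was 0.339 against 0.213 in oeCtrl.

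On day 6 of F4H the cells named shYy1 were compared with their control, which carried no construct if the names of the tables hold. Mesendoderm genes were lower in the shYy1 cells although Yy1 was not. The growth factor gene Fgf8 stood at 34.7 ± 1.74 against 161 ± 0.822 CPM (log2 -2.20 ± 0.06, adjusted p = 5.12e-39) and the homeobox gene Lhx1 at 29.3 ± 1.75 against 122 ± 10.3 CPM (log2 -2.05). Mesp1, a regulator of early mesoderm, fell by 4.25, and Snai1, which drives epithelial cells to become mesenchymal, by 1.94. In the mesendoderm list 2 of 17 members rose and 14 fell (2 and 14 adjusted over the list alone, camera adjusted p = 8.66e-06, adjusted p = 0.0467 with an estimated correlation). Gata4 (18.9 ± 0.235 against 47.4 ± 1.85 CPM, log2 -1.32 ± 0.09, adjusted p = 1.55e-20), Pdgfra (log2 -2.11), Sox17 (3.85 ± 0.538 against 10.9 ± 2.36 CPM) and Cdx2 (log2 -0.79) fell. Gata6 fell by 0.34 (adjusted p = 0.00991), a call that DESeq2 did not make (0.0694). The call was lost without F4H EPS shCtrl or shYy1 replicate 2.

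The basement membrane collagens Col4a1 (log2 1.45) and Col4a2 (log2 1.29) rose, and in the primitive endoderm list, which holds them, 12 of 25 members rose and 10 fell (12 and 10 adjusted over the list alone, median 0.42, camera adjusted p = 0.691). This median rested on single libraries, at 0.105 and -0.116 without F4H EPS shYy1 replicates 1 and 2, and 0.0907 and 0.244 without F4H EPS shCtrl replicates 1 and 2. Keratins of simple epithelium were higher, with Krt8 at 3514 ± 107 against 1519 ± 15.2 CPM and Krt18 up by 1.18, and the trophoblast list that holds them had 12 of 20 members up and 5 down, as adjusted over the list alone (camera, adjusted p = 0.0322, adjusted p = 0.152 with an estimated correlation). This call was lost without the X-linked members (0.0659). Among formative genes, the growth factor gene Fgf5 fell (11.6 ± 0.0311 against 33.5 ± 3.08 CPM). In the list 4 of 18 members rose and 12 fell (4 and 12 adjusted over the list alone, camera adjusted p = 0.0322, adjusted p = 0.152 with an estimated correlation). The Wnt targets T, or Brachyury (log2 -1.06), and Sp5 (-1.07) fell. In their list 2 of 14 members rose and 9 fell (2 and 9 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.218 with an estimated correlation). Nanog (log2 -0.21, adjusted p = 0.104), Pou5f1 and Klf4 (adjusted p = 0.164 and 0.188) were not called, and Sox2 passed narrowly (log2 -0.25, adjusted p = 0.0454). That call ended without any 1 of the 4 libraries (at most 0.238), with only those libraries (0.0582), with RLE factors (0.0535), without a count filter (0.0633), by DESeq2 (0.126), by limma-voom and without X-linked and Y-linked genes (0.0524).

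Genes of the interferon response were lower in shYy1 than in shCtrl cells on day 6, where 1 of 22 members rose and 19 fell (1 and 19 adjusted over the list alone, camera adjusted p = 5.95e-09, adjusted p = 0.0380 with an estimated correlation). The ubiquitin-like Isg15 stood at 8.82 ± 0.379 against 56.5 ± 1.32 CPM (log2 -2.67 ± 0.10, adjusted p = 3.16e-32), Oasl2 fell by 2.31 and Bst2, which tethers budding virus, by 2.12. Isg15 was at 6.90 ± 1.07 CPM in day 6 oeCtrl and 12.8 ± 0.877 CPM in day 6 oeYy1 cells, so shCtrl was the group apart. Mean r across genes of day 6 shYy1 was 0.978 with oeCtrl and 0.952 with shCtrl libraries. The day 6 differences may thus lie in either group. Targets of p53 were higher, with Mdm2, the ubiquitin ligase of p53, at 567 ± 6.89 against 257 ± 1.12 CPM (log2 1.15 ± 0.04), and Perp (log2 1.36) and Ccng1 (1.03). In this list 17 of 19 members rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 1.16e-08, adjusted p = 0.0380 with an estimated correlation). Mitotic genes were lower, among them the kinase gene Aurkb (log2 -0.91) and the cyclin gene Ccnb2 (-0.79). In the G2/M list 0 of 19 members rose and 17 fell (0 and 18 adjusted over the list alone, camera adjusted p = 2.08e-07, adjusted p = 0.0380 with an estimated correlation).

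In the cholesterol list 18 of 23 members rose and 1 fell (18 and 1 adjusted over the list alone, camera adjusted p = 1.81e-04, adjusted p = 0.0467 with an estimated correlation). Ribosomal protein genes were lower by small amounts, as Rpl11 (log2 -0.51), and 0 of 53 members rose and 44 fell (0 and 45 adjusted over the list alone, camera adjusted p = 8.81e-16, adjusted p = 0.290 with an estimated correlation). Of the glycolysis list 4 of 21 members rose and 15 fell (4 and 15 adjusted over the list alone, camera adjusted p = 0.00613, adjusted p = 0.352 with an estimated correlation), with the glucose transporter Slc2a1 up (log2 0.95) and Aldoc down (-1.98). In the fibroblast list 13 of 22 members rose and 6 fell (13 and 6 adjusted over the list alone, camera adjusted p = 0.0122, adjusted p = 0.136 with an estimated correlation), and the contractile genes Acta2 (841 ± 1.62 against 102 ± 1.45 CPM) and Tagln (log2 2.23), which many cell types express, led the rises. The 5 sex-linked genes all rose, also 5 adjusted over the list alone (camera, adjusted p = 1.14e-05, adjusted p = 0.0467 with an estimated correlation). Xist, the RNA that silences an X chromosome, stood at 466 ± 12.1 against 0.353 ± 0.174 CPM, and the X-linked median log2 fold change was 0.26. Kdm5c rose by 0.62 and Hdac6 fell by 0.29. Dnmt3l was low in both groups (1.28 ± 0.319 against 0.348 ± 0.222 CPM, log2 1.89 ± 0.42, adjusted p = 1.06e-04). The steepest fall was in the imprinted growth factor adaptor Grb10 (14.8 ± 0.521 against 504 ± 9.75 CPM, log2 -5.08).

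Of 15927 genes tested on day 6, 9762 were called between shYy1 and shCtrl, 4924 higher and 4838 lower, and 2407 changed at least 2-fold. The 16 lists that did not pass had adjusted p between 0.0514 and 0.788, and the calls of the mesendoderm, interferon, p53, G2/M, cholesterol and sex-linked lists held with an estimated correlation. Of the EPS-high genes 172 rose and 238 fell (173 and 238 adjusted over the list alone, camera adjusted p = 0.189). Of the ES-high genes 322 rose and 201 fell (324 and 202 adjusted over the list alone, median 0.19, camera adjusted p = 0.0461), a call that was lost without F4H EPS shCtrl replicate 1 (0.0566), without X-linked and Y-linked members (0.104), for the list at a 4-fold threshold (0.186), with RLE factors (0.0528) and with the replicate block.

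Day 6 cells from oeYy1 ES cells were compared with those named oeCtrl, with the same doubt about the control construct, and mesendoderm and Wnt target genes were higher. The homeobox gene Evx1 stood at 116 ± 2.89 against 38.6 ± 0.307 CPM (log2 1.62 ± 0.07, adjusted p = 1.40e-28), and Fgf8 (log2 1.46), Mixl1 (1.35) and Lhx1 (1.39) rose. In the mesendoderm list 12 of 17 members rose and 0 fell (13 and 1 adjusted over the list alone, camera adjusted p = 1.54e-08, adjusted p = 0.0834 with an estimated correlation). The Wnt inhibitor Nkd1 rose by 1.65 and the Wnt effector Lef1 by 1.18. In their list 10 of 14 members rose and 1 fell (10 and 1 adjusted over the list alone, camera adjusted p = 1.62e-07, adjusted p = 0.0834 with an estimated correlation). Egr1 stood at 312 ± 16.4 against 64.6 ± 4.97 CPM (log2 2.31). In the ERK list 13 of 18 members rose and 4 fell (13 and 4 adjusted over the list alone, camera adjusted p = 0.00110, adjusted p = 0.0834 with an estimated correlation). Naive pluripotency genes were lower, as Zfp42 (log2 -1.66), Dppa5a (-2.47) and Nanog (20.2 ± 0.548 against 34.6 ± 0.258 CPM, log2 -0.74 ± 0.09, adjusted p = 1.84e-09). In their list 3 of 20 members rose and 14 fell (4 and 15 adjusted over the list alone, camera adjusted p = 6.84e-05, adjusted p = 0.127 with an estimated correlation). Pou5f1 fell by 0.43, while Sox2 and Klf4 were not called (adjusted p = 0.445 and 0.0552).

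Gata4 (26.1 ± 2.96 against 10.5 ± 1.00 CPM, log2 1.34 ± 0.11), Gata6 (log2 1.09), Pdgfra (0.98) and Cdx2 (0.58) rose in day 6 oeYy1 cells. Sox17 fell by 1.02 (adjusted p = 0.00648, or 0.0995 without F4H ES oeYy1 replicate 2), and so did Lama1 (log2 -1.12). In the primitive endoderm list 7 of 25 members rose and 13 fell (7 and 14 adjusted over the list alone, median -0.27, camera adjusted p = 0.168). Krt8 (log2 -0.89) and Krt7 (-1.18) fell and the T-box gene Eomes rose (1.39). In the trophoblast list 5 of 20 members rose and 10 fell (5 and 10 adjusted over the list alone, camera adjusted p = 0.0112, adjusted p = 0.127 with an estimated correlation, or 0.0525 without X-linked and Y-linked members). Targets of p53 were lower, as Mdm2 (log2 -0.44) and Perp (-0.66). In their list 4 of 19 members rose and 12 fell (4 and 12 adjusted over the list alone, camera adjusted p = 8.54e-04, adjusted p = 0.0834 with an estimated correlation). Mitotic genes were higher, as Mki67 (log2 0.41). In the G2/M list 11 of 19 members rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.00115, adjusted p = 0.0834 with an estimated correlation). Acta2 (log2 -1.86) and Tagln (-0.86) fell. In the fibroblast list 4 of 22 members rose and 11 fell (5 and 12 adjusted over the list alone, camera adjusted p = 0.00110, adjusted p = 0.0834 with an estimated correlation). Dnmt3l, higher with overexpression before F4H, fell from 19.4 ± 1.93 to 2.52 ± 0.604 CPM.

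Among enzymes of H3K4 methylation and histone deacetylation 14 of 27 members rose and 2 fell (14 and 3 adjusted over the list alone, camera adjusted p = 0.00967, adjusted p = 0.123 with an estimated correlation), as the deacetylase gene Hdac5 (log2 0.60), while Kdm5c and Hdac6 were not called (adjusted p = 0.857 and 0.193). In the glycolysis list 12 of 21 members rose and 5 fell (12 and 5 adjusted over the list alone, camera adjusted p = 0.0117, adjusted p = 0.355 with an estimated correlation), as the lactate transporter Slc16a3 (log2 0.93). In the germline list 0 of 11 members rose and 6 fell (0 and 7 adjusted over the list alone, camera adjusted p = 0.0178, adjusted p = 0.152 with an estimated correlation, or 0.0620 without X-linked and Y-linked members), as the germ cell helicase Ddx4 (log2 -1.01). Of the sex-linked genes 3 of 5 fell, also 3 adjusted over the list alone (camera, adjusted p = 0.0243, adjusted p = 0.152 with an estimated correlation). The formative list was higher (7 of 18 up, 3 down; 7 and 3 adjusted over the list alone, adjusted p = 0.0488, adjusted p = 0.167 with an estimated correlation, or 0.0798 without F4H ES oeCtrl replicate 1 and 0.0636 without X-linked and Y-linked members). So was the imprinted list (14 of 31 up, 8 down; 14 and 8 adjusted over the list alone, adjusted p = 0.0488, adjusted p = 0.152 with an estimated correlation, or 0.0782 without F4H ES oeCtrl replicate 1). The cohesin list was higher too (8 of 15 up, 0 down; 8 and 0 adjusted over the list alone, adjusted p = 0.0484, adjusted p = 0.540 with an estimated correlation, or 0.143 without F4H ES oeCtrl replicate 1 and 0.0911 without F4H ES oeYy1 replicate 2 and 0.0509 by fry and 0.0911 without X-linked and Y-linked members), as was the interferon list (8 of 22 up, 2 down; 8 and 2 adjusted over the list alone, adjusted p = 0.0484, adjusted p = 0.206 with an estimated correlation, or 0.0936 without F4H ES oeCtrl replicate 2 and 0.0555 without F4H ES oeYy1 replicate 1). The ribosomal protein list was lower (8 of 53 up, 19 down; 8 and 21 adjusted over the list alone, adjusted p = 0.0484, adjusted p = 0.760 with an estimated correlation, or 0.919 without F4H ES oeCtrl replicate 1 and 0.830 without F4H ES oeYy1 replicate 2, where camera pointed up, and 0.475 by fry). So was the oxidative phosphorylation list (3 of 51 up, 23 down; 3 and 27 adjusted over the list alone, adjusted p = 0.00360, adjusted p = 0.649 with an estimated correlation, or 0.0969 without F4H ES oeCtrl replicate 1 and 0.0802 without F4H ES oeYy1 replicate 2 and 0.117 by fry). No list call of this comparison held with an estimated correlation. Of 15927 genes 6675 were called, 3236 higher and 3439 lower in oeYy1 cells, and 963 changed at least 2-fold. The 10 other lists did not pass (0.115 to 0.807), nor did the EPS-high (139 up, 143 down, 139 and 145 adjusted over the list alone, adjusted p = 0.898) and ES-high genes (167 up, 230 down, 171 and 235 adjusted over the list alone, adjusted p = 0.239). Across genes, the day 6 changes with the hairpin and with the construct, which share no library, had a correlation of -0.48, and genes are not independent replicates.

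**Figure D5:**
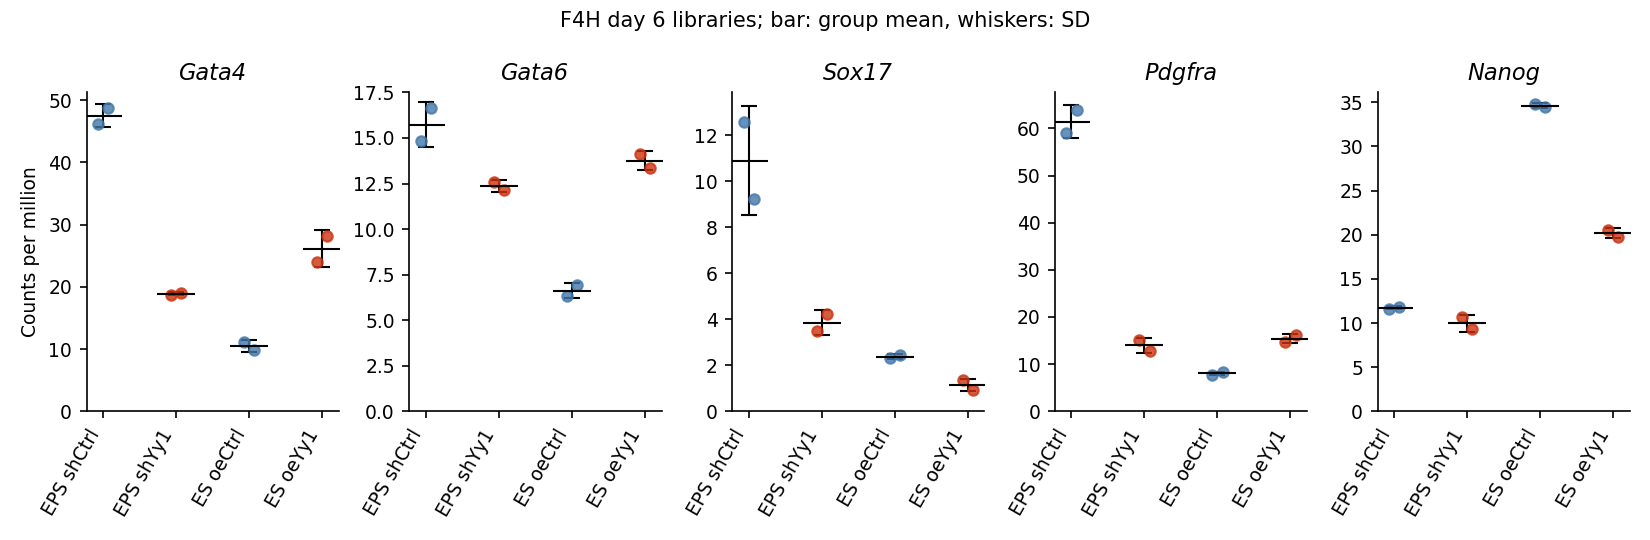
Levels in CPM of Gata4, Gata6, Sox17, Pdgfra and Nanog in the 8 day 6 libraries, with each point a library, the bar the group mean and the whiskers the SD (n = 2). Gata4 stood at 47.4 CPM in shCtrl, 18.9 in shYy1, 10.5 in oeCtrl and 26.1 in oeYy1 cells.

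The 2 day 6 controls, which are the same libraries as above and whose construct is in doubt, differ in their state of origin. Cells from EPS shCtrl held more Gata4 (47.4 ± 1.85 against 10.5 ± 1.00 CPM, log2 2.18 ± 0.09, adjusted p = 1.02e-28), Pdgfra (log2 2.95), Sox17 (2.20) and Gata6 (1.26) than cells from ES oeCtrl. The secreted antagonist Cer1 (log2 6.52), Mesp1 (4.83) and the imprinted growth factor Igf2 (2.50) were also higher. Cdx2 (log2 0.28) and Hdac6 (0.53) were higher by less. Nanog (log2 -1.55), Pou5f1 (-1.07), Sox2 (-1.51), Klf4 (-1.16), Kdm5c (-0.37), Dppa5a (-5.47), Dnmt3l (-5.75) and Col4a1 (-1.75) were lower. In the mesendoderm list 11 of 17 members rose and 3 fell (11 and 3 adjusted over the list alone, camera adjusted p = 0.00424, adjusted p = 0.209 with an estimated correlation). In the interferon list 20 of 22 members rose and 1 fell (20 and 1 adjusted over the list alone, adjusted p = 1.18e-09, adjusted p = 0.0978 with an estimated correlation). In the ribosomal protein list 44 of 53 members rose and 2 fell (44 and 2 adjusted over the list alone, adjusted p = 6.15e-12, adjusted p = 0.383 with an estimated correlation). Among naive pluripotency genes 2 of 20 members rose and 16 fell (2 and 16 adjusted over the list alone, camera adjusted p = 3.77e-05, adjusted p = 0.221 with an estimated correlation). Among p53 targets 2 of 19 members rose and 14 fell (2 and 14 adjusted over the list alone, adjusted p = 1.71e-05, adjusted p = 0.0978 with an estimated correlation). Among neuroectoderm genes 1 of 14 members rose and 9 fell (1 and 9 adjusted over the list alone, adjusted p = 0.0320, adjusted p = 0.221 with an estimated correlation). The primitive endoderm list went both ways, with 11 of 25 up and 12 down, as adjusted over the list alone. Its median log2 fold change was 0.11 and its mean -0.16, camera pointed up (adjusted p = 0.954) and fry pointed down (adjusted p = 0.0101). The median was 0.203 and 0.0756 without F4H ES oeCtrl replicates 1 and 2, and 0.171 and -0.0491 without F4H EPS shCtrl replicates 1 and 2, and camera pointed down without F4H ES oeCtrl replicate 2 (0.924). Yy1 was lower by a small amount (log2 -0.11, adjusted p = 0.0319), a call that ended without F4H ES oeCtrl replicate 2 or F4H EPS shCtrl replicate 2 (at most 0.238), without a count filter and by DESeq2 (at most 0.102). Oxidative phosphorylation genes were higher (27 of 51 up, 7 down; 28 and 7 adjusted over the list alone, adjusted p = 0.0224, adjusted p = 0.712 with an estimated correlation, or 0.0699 without F4H ES oeCtrl replicate 2 and 0.0789 without F4H EPS shCtrl replicate 2 and 0.0697 by fry). So were G2/M genes (11 of 19 up, 3 down; 11 and 3 adjusted over the list alone, adjusted p = 0.0336, adjusted p = 0.221 with an estimated correlation, or 0.0584 without F4H EPS shCtrl replicate 2). Germline genes were lower (0 of 11 up, 8 down; 0 and 8 adjusted over the list alone, adjusted p = 0.0404, adjusted p = 0.226 with an estimated correlation, or 0.0532 without F4H EPS shCtrl replicate 1 and 0.0729 without F4H EPS shCtrl replicate 2 and 0.0793 without X-linked and Y-linked members and 0.0582 with the replicate block). The sex-linked list was lower (0 of 5 up, 4 down; 0 and 4 adjusted over the list alone, adjusted p = 0.00424, adjusted p = 0.209 with an estimated correlation), and the 18 other lists did not pass (0.0503 to 0.954). In all 10205 genes were called, 5037 higher and 5168 lower, and no list call held with an estimated correlation.

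Primitive endoderm genes were compared between day 6 and the cells before F4H. In ES oeCtrl cells 19 of 27 members rose and 5 fell (19 and 5 adjusted over the list alone, median log2 change 3.34, camera adjusted p = 0.00707, adjusted p = 0.0744 with an estimated correlation). In ES oeYy1 cells 17 of 27 members rose and 8 fell (17 and 8 adjusted over the list alone, median 2.11, adjusted p = 0.0257, adjusted p = 0.109 with an estimated correlation). In EPS shYy1 cells 17 of 27 members rose and 5 fell (18 and 5 adjusted over the list alone, median 1.85, adjusted p = 0.0111, adjusted p = 0.0609 with an estimated correlation). In EPS shCtrl cells the list did not pass, although 15 of 27 members rose and 9 fell (15 and 9 adjusted over the list alone, median 1.25, adjusted p = 0.0754). It passed there by fry (1.60e-08) and without EPS shCtrl replicate 1 or either F4H EPS shCtrl replicate. The test of the change of effect did not pass for this list with depletion (adjusted p = 0.177) or overexpression (adjusted p = 0.374). Of the 28 fixed lists 20 passed from before F4H to day 6 in each EPS group and 17 in each ES group, of which 5 held with an estimated correlation in shCtrl, 4 in shYy1 and 6 in each of oeCtrl and oeYy1 cells. The day 6 libraries were submitted later and with their own library kit text. Stage and submission are confounded, so a technical part of the change to day 6 cannot be separated. The test of day 6 minus undifferentiated effects called 7133 of 17207 genes for depletion and 6475 for overexpression. On day 6, however, Yy1 was not lower in shYy1 cells. Dnmt3l differed by 4.62 ± 0.67 for depletion (adjusted p = 8.79e-05) and by -9.36 ± 0.38 for overexpression (adjusted p = 7.87e-10), and Nanog by -1.27 ± 0.12 and -1.01 ± 0.11. In the ERK list the difference was upward for depletion, where 14 of 18 members rose and 2 fell (14 and 2 adjusted over the list alone, camera adjusted p = 4.50e-04, adjusted p = 0.0589 with an estimated correlation). In the naive list it was downward for overexpression, where 1 of 20 members rose and 15 fell (1 and 15 adjusted over the list alone, camera adjusted p = 2.25e-05, adjusted p = 0.0912 with an estimated correlation). The other lists that passed for depletion were mesendoderm, cholesterol, ribosomal protein, interferon and G2/M (adjusted p = 0.0244, then 0.0168, 0.0168, 6.89e-04 and 0.00239). None of these held with an estimated correlation (0.353, 0.798, 0.798, 0.0986 and 0.614). The first 3 ended without EPS shCtrl replicate 1 (at most 0.143), cholesterol and ribosomal protein also without EPS shYy1 replicate 1 (0.0550 and 0.0582), and ribosomal protein without F4H EPS shCtrl replicate 2 (0.0633) and by fry (0.200). For overexpression the 2-cell-like, fibroblast, cholesterol and G2/M lists passed too (adjusted p = 8.93e-04, then 1.63e-05, 2.90e-06 and 0.0113). With an estimated correlation the fibroblast list held (adjusted p = 0.0354) and the others did not (0.197, 0.394 and 0.600), and that of G2/M ended without ES oeCtrl replicate 2 (0.0625).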

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

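Of the tests below, the share of ES-high genes near 0 and the splits of the libraries were set before the result was seen, and the other 7 tests were chosen only after it was seen. The first values are of genes whose difference between hairpin or construct cells and control changed from undifferentiated cells to day 6 of F4H. On day 6 Yy1 was not lower in shYy1 than in shCtrl cells (log2 -0.03, adjusted p = 0.567 by the quasi-likelihood F-test). The hairpin values therefore set a depletion before F4H against cells without a lower Yy1 level on day 6. For the hairpin the day 6 difference minus the undifferentiated difference, on the log2 scale, was 0.95 for Yy1, 4.62 for Dnmt3l, -1.49 for Hdac6, -1.27 for Nanog, 0.43 for Pou5f1, -0.57 for Sox2, 0.49 for Klf4, -0.54 for Gata4 and 1.75 for Gata6. For overexpression it was -1.60 for Yy1, -9.36 for Dnmt3l, -1.01 for Nanog, -0.98 for Pou5f1, -0.43 for Sox2, -0.62 for Klf4, 2.45 for Gata4, 2.92 for Gata6 and -2.15 for Sox17. Gata6 stood at only 0.638 and 0.166 CPM in undifferentiated oeCtrl and oeYy1 cells, and Dnmt3l at 0.348 and 1.28 CPM in day 6 shCtrl and shYy1 cells. Values that rest on such low levels are uncertain.

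X-linked and Y-linked genes were higher in EPS shYy1 than in EPS shCtrl cells. If the Yy1 level set the Y-linked difference it would be gone on day 6, where Yy1 was not lower, yet Ddx3y stood 4.03 higher there. Feeder RNA is argued against as the source of the Y-linked rise of 145 CPM: 8 of 22 fibroblast genes rose, but the largest rise among the 10 with a mean of at least 100 CPM in ES libraries, that of Col5a1, was 5.28% of its ES level and would bring 3.83 Y-linked CPM at the ratio of those libraries. Different sex chromosome content of both cell populations stays open. Y-linked genes summed to 171 CPM in day 6 shYy1 and 15.2 CPM in day 6 shCtrl libraries. The lower quartile of the X-linked changes on day 6 was -0.26. That value cannot decide, since Xist, which silences an X chromosome, stood at 466 against 0.353 CPM and may lower the X-linked shift. Kdm5c and Hdac6 lay at percentiles 47.6 and 69.2 of the X-linked changes, so the shift shared by X-linked genes may account for their rise before F4H, while on day 6 Hdac6 fell by 0.29 (percentile 24.3) and Kdm5c was at percentile 69.0, with an X-linked median of 0.26.

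Fibroblast genes were lower in EPS than in ES cells. If the EPS libraries held less RNA from feeder cells, ES-high genes might be near 0 in ES cells of the other experiment, and 29.8% of them had a mean under 1 CPM in ES oeCtrl, against 22.5% of EPS-high genes in EPS shCtrl, which lies between both predictions. A fibroblast programme that ES cells hold in every culture is argued against, since the same 10 fibroblast genes had a median of 0.131% of their ES level in ES oeCtrl, each below its EPS mean, as Col1a1 at 1.21 against 939 CPM. Less feeder RNA and a programme limited to these cultures, which was not tested, cannot be told apart. The labels do not say which libraries grew on feeders. The endoderm list carries the same limit, as fibroblasts also express Sparc.

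Yy1 was not lower in day 6 shYy1 than in day 6 shCtrl cells. A swap of the day 6 labels is argued against by Y-linked Eif2s3y, which stayed 3.64 higher in the libraries named shYy1. Low precision is argued against by the interval of 2 standard errors around the day 6 value of Yy1, from -0.13 to 0.06, which leaves out the undifferentiated -0.99. Loss of the hairpin or outgrowth of cells that escaped it stays open and was not tested. So does the construct of the control, which the titles name shCtrl and the table names leave out: its Y-linked genes summed to 15.2 CPM, against 3.07 in EPS shCtrl and 21.2 in EPS cells.

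With 3 against 3 libraries there are 10 splits of the ES and EPS libraries, so the share as large as the real one can never be under 0.1. The real split gave 5033 called genes in the model of all 14 undifferentiated libraries, the other 8 kept in their groups. The highest other gave 0, so 1 of 10 splits was as large. The real split parts all 3 pairs of the same replicate number, and so do 3 of the others, while the other 6 part 1 pair each.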

How the results depend on the processing

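The alternatives by chromosome, without replicate 3 of both states, or by 1 CPM over hairpin and overexpression libraries were chosen after seeing the data. Of the named genes, 2959 results kept their side of the threshold without 1 library, 245 were lost and 4 gained, and under the other alternatives 6185 kept it, 94 were lost and 13 gained, with no direction reversed. For the fixed lists outside the derived and day 6 endoderm results these numbers were 1570, 35 and 62 without 1 library and 1199, 137 and 117 otherwise, with 1 reversal. Where leaving out a library leaves 1 in its group, that lone sample is assumed to vary like the other groups. Depth limits the genes at a few counts, such as the 2-cell-like list. In the other experiments r between libraries of the same number was 0.131 for the hairpin, which also passed 0.1, and 0.011 for overexpression. On day 6 it was 0.0902 for the construct and 0.0134 for the hairpin. With 2 libraries per group both pairs share the same r, so pairing was not settled there either.

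Counts of called genes stayed within 1.5 times the reported number except in 2 comparisons, whose counts without 1 library follow. For depletion they ran from 2571 (without EPS shCtrl replicate 2) to 4853, with 2618 and 2703 without EPS shYy1 replicates 1 and 2, and for overexpression from 3065 (without ES oeYy1 replicate 2) to 3614, with 3290 and 3378 without ES oeCtrl replicate 1 and ES oeYy1 replicate 1. With only the 4 libraries compared the overexpression count was 8149. The cause was not tested for either comparison. The shift of oeYy1 along the line from ES to EPS ran from 0.0827 to 0.147 without 1 ES or EPS library, and was 0.148 for expressed genes outside chromosomes X and Y. In EPS against ES the replicate block added the core pluripotency and ribosomal protein lists, Kdm5c and Pdgfra, and changed no other call of a named gene or list. The replicate block gave 6245, 6008 and 6401 genes for EPS against ES, depletion and overexpression.

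For EPS-high genes with overexpression the median was 0.40 (adjusted p = 0.106) with an estimated correlation and 0.0587 (0.553) with no fold threshold, and ran from 0.33 to 0.48 without 1 library. On day 6 the ES-high genes in shYy1 against shCtrl had 0.27 (0.186) at the higher fold threshold, 0.16 (0.104) without X-linked and Y-linked members, 0.20 (0.0528) with RLE factors, 0.19 with the replicate block and 0.18 to 0.22 without 1 library. With fry, which asks another question, the day 6 lists passed for primitive endoderm in shYy1 (0.42, 0.00443, with medians from -0.116 to 0.244 without 1 library) and oeYy1 (-0.27, 0.0332, with -0.304 to -0.253), EPS-high genes in shYy1 (-0.17, 0.00225) and ES-high genes in oeYy1 (-0.12, 9.12e-04). In shCtrl against oeCtrl fry pointed down for primitive endoderm (median 0.11, 0.0101, with -0.0491 to 0.203 without 1 library), opposite to camera. The rise of primitive endoderm genes to day 6 had adjusted p of 0.0609 (median 1.85) in EPS shYy1, 0.0744 (3.34) in ES oeCtrl and 0.109 (2.11) in ES oeYy1 cells with an estimated correlation. In EPS shCtrl cells it was 1.25 (1.60e-08) by fry and ran from 1.27 to 1.498 without 1 library. For ribosomal protein genes on day 6 in oeYy1 the direction of camera reversed to up without F4H ES oeYy1 replicate 2, in an edgeR and limma fit, at adjusted p = 0.830. Their median stayed negative there (-0.0251) and ran down to a median of -0.18 without replicate 1. The cause was not tested for any of these.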

Other observations

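The values below come from lists fixed beforehand, and the test of X-linked levels was chosen only after the result was seen. The interferon-stimulated list did not pass in any of the 3 undifferentiated comparisons, while single members moved. Ddx58, a cytosolic sensor of viral RNA, stood at 93.7 against 33.6 CPM in EPS against ES cells, fell by 2.23 after depletion (from 70.9 to 15.4 CPM) and rose by 2.27 with overexpression (from 15.5 to 73.9 CPM). Xaf1, an interferon-induced promoter of apoptosis, rose by 2.27 after depletion and by 0.71 with overexpression, and Bst2 fell by 2.68 with overexpression. Of 22 members 4 rose and 1 fell in EPS against ES (4 and 1 adjusted over the list alone, camera adjusted p = 0.868), 2 rose and 2 fell after depletion (2 and 2, adjusted p = 0.580) and 5 rose and 1 fell with overexpression (4 and 1, adjusted p = 0.488).

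Germ cell genes were divided as well. Ddx4, a germ cell RNA helicase, rose by 1.95 in EPS against ES cells, Mael, which acts with piRNAs, by 3.04, and Sycp3, part of the meiotic chromosome axis, by 2.92. After depletion the germ cell RNA-binding protein Dazl rose from 13.4 to 37.9 CPM and Hormad1 by 1.77, and with overexpression Dazl fell by 2.06. Of 21 germline members 9 rose and 4 fell in EPS against ES (10 and 6 adjusted over the list alone, camera adjusted p = 0.260), with adjusted p = 0.844 after depletion and adjusted p = 0.806 with overexpression. Sox11, a neural transcription factor, rose by 2.08 in EPS cells and fell by 1.45 after depletion, while the adhesion molecule Ncam1 fell by 0.57 and rose by 1.83 (neuroectoderm list, adjusted p = 0.676 and adjusted p = 0.844). The kinase gene Pim1, a STAT3 target, rose by 1.52 after depletion and fell by 0.85 with overexpression (LIF-STAT3 list, adjusted p = 0.764 and adjusted p = 0.474). In EPS against ES the medians of the neuroectoderm (-0.27), 2-cell-like (0.00), H3K4 (-0.01), mitochondrial (-0.01), cholesterol (0.04) and INO80 lists (0.00) differed in sign from their mean or their test, none of which passed.

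The ERK target list and Dnmt3l were lower in shYy1 cells, whose X-linked genes were higher. A hypothesis is that the higher X-linked expression, and not Yy1 itself, may have lowered them. In ES cells with overexpression, where the X-linked median was 0.00719 above the autosomal one, Dnmt3l still rose, so it can change without an X-linked shift. Of the ERK list 7 of 18 members rose and 1 fell there, a call that was lost with an estimated correlation (adjusted p = 0.106). That leaves open which of both acted in the shYy1 cells, because every shYy1 library carries the shift.

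Genes on chromosomes 6 and 8 were lower as a block in EPS against ES (medians -0.27 and -0.26 below the autosomal one) and in day 6 shCtrl against oeCtrl (-0.34 and -0.42). In day 6 oeYy1 against oeCtrl, genes on chromosomes 3 and 6 were higher (0.17 and 0.12 above the autosomal median) and those on 16 lower (-0.20). Of all chromosomes in the 6 main comparisons, these and X and Y after depletion passed with an estimated correlation, and no cause was tested.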
